A study of Homo sapiens with 4 samples.

How the data were processed

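Guide abundance was measured by sequencing PCR products of genomic DNA from 786-O cells, a human clear cell renal carcinoma line, that expressed dCas9 and carried a pooled CRISPR interference (CRISPRi) guide library. In CRISPRi a catalytically dead Cas9 is brought to a promoter by a guide RNA and represses transcription there. Per the labels, transduced cells were selected with puromycin and libraries were built by successive rounds of PCR. The samples were 4 libraries, 1 per time from each of 2 clones (clone 2 and clone 6), collected before growth (day 0) and after 15 days (day 15). The labels describe the clones as independent and say nothing more of separate cultures, so all p-values concern these 4 libraries only. Those of unpaired fits to library values measure the spread between the libraries, moderated by a variance pooled across targets. Those of fits paired by clone rest mainly on a variance pooled across targets. Those from permuting or ranking single guides measure the spread between guides.

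The deposited table holds, for each guide and library, RPM (reads divided by the library total and multiplied by 1000000) with 1 added by the authors. This unit was found from the values: after 1 is taken away each column sums to 1000000. The name bcl2fastq, the name MAGeCK and the build GRCh38 are given per the submitters' processing notes, without role, version or settings. How reads were matched to guides, and whether any were filtered, was not given in the sources used here. RPM values are relative to the library total, so growth of some guides lowers the value of all others.

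The value of 1 read was found from the spacing of the values, and all values were whole multiples of it within 0.01 read. The depth was 10171646 reads for clone 2 at day 0, 10165682 for clone 2 at day 15, 6791912 for clone 6 at day 0 and 13179170 for clone 6 at day 15. The median reads per guide were 801, 707, 533 and 753 in that order. A guide at 0 could have up to 0.295, 0.295, 0.442 and 0.228 RPM in these libraries, from an upper limit of 3 reads. Because the reads came from PCR without molecular identifiers, intervals and limits cover counting error only.

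Guides with a mean of at least 10 RPM over the 4 libraries were kept, which left 11720 of 12468 guides. Of the others, 693 had 0 reads in all 4 libraries. Targets needed at least 3 kept guides, which left 765 of 800 targets, and 35 were left out. For each guide log2(RPM + 1) was taken, so that fold changes are on that scale and understate the change of guides with few reads. Values were averaged over the guides of a target in each library, and day 15 was compared with day 0 by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, Benjamini-Hochberg adjustment, 2-sided, threshold 0.05). This model had no term for the clone and 2 residual degrees of freedom. The eBayes step added a variance pooled across targets, with a prior weight of 3.41 degrees of freedom. A paired fit with the clone number as a replicate block was fixed as an alternative in advance. The clone numbers pair the libraries because each number marks 1 clone, and the deviations from the time means correlated between day 0 and day 15 across guides with Pearson r = 0.573.

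Gene lists were tested with camera (preset correlation 0.01, lists of at least 5 members), with an estimated correlation and fry as alternatives. The lists were snoRNA host genes, microRNA host genes, long noncoding RNAs (lncRNAs) studied in cancer, housekeeping structured RNAs, antisense names, divergent names, intergenic names, lncRNAs named for a housekeeping gene, lncRNAs at renal carcinoma genes, and protein-coding positive controls. A list based on distance to coding promoters was void, since 21.8% of the targets were found in the gene table used. The difference between clones was tested per target against 100000 random sets of guides of the same size. Negative-control and targeting guides were compared by a 2-sided permutation of guides. Intervals of shares are 95% Wilson intervals.

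Alternatives were other pseudocounts, guide filters, summaries over guides, library scalings and gene tests, leaving out each library in turn, and each clone alone. Among the gene tests were random guide sets and α-RRA, a robust rank aggregation of guides. Chosen after the data were seen were random sets of negative-control guides, limma voom on the recovered reads, scaling and block together, and consecutive sets of 10 guides of a target in table order. Which promoter each guide targets was not given in the sources used here, so these sets are only neighbours in the table. The other choices, including the lists, the tests and the threshold, were made before the data were examined. Negative-binomial count tests were planned only for a file of raw counts and were not run. In their place, limma voom was run on the recovered reads.

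Named targets were CRNDE, the lncRNA in the series title, the 14 lowest and the 6 highest passing targets with the same direction in both clones and in at least 50% of guides (or the 5 with the smallest p where fewer than 5 passed), the 2 members with the smallest p of each list with a passing member, and the 2 largest clone differences in each direction past the threshold. Named after their values were seen were the other protein-coding controls, the 14 lowest other targets that passed in the paired fit, members of lists without a passing member, targets beside housekeeping genes, and targets with a passing set of guides. Positions come from a RefSeq gene table of GRCh38.p14, in which 144 target names were found directly and 30 through an older symbol. The other 626 names are printed as deposited, without positions. The values of 1 control gene that this rule names are not reported here.

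The tests were tested on simulated data with 765 targets, guide drift as wide as that of the negative-control guides and reads drawn at the real depths. With 40 targets lowered, 20 by 1 and 20 by 2 on the log2 scale, the unpaired limma fit found 80% and 100% of them with 0 false calls among 725 unchanged targets. The paired fit found 100% and 100%, with 10 false calls, all in the lower direction. Random guide sets found 90% and 100% with 1 false call, in the higher direction. α-RRA, tested here for lower only, found 75% and 100% with 0. With 100 targets lowered by each amount, random guide sets made 102 false calls of higher among 565 unchanged targets, since that test is relative to the mean guide. In the same simulation the unpaired and the paired fit each made 1 false call, of higher, and found 95% and 98% of the targets lowered by 1, against 35% for random guide sets and 16% for α-RRA. With no target changed all 4 tests made 0 calls, α-RRA again tested for lower only. Each setting was a single simulated data set, so these counts are not error rates. Drift was drawn separately in each clone, so the counts do not cover drift that the clones share. In the data the changes of negative-control guides correlated between the clones with Pearson r = 0.114.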

Results

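A CRISPRi screen of lncRNAs was carried out in 786-O cells to find targets whose repression alters growth. The abundance of 12468 guides was measured in 2 clones at day 0 and at day 15. The guides were aimed at 800 targets, 585 of them with 10 guides, 207 with more and 8 with fewer, and 450 further guides were negative controls. Among the targets were 12 protein-coding genes needed for growth in most cells, namely 9 ribosomal protein genes and the replication genes PCNA, RPA1 and RPA3, here called controls. Sequencing depth ranged from 6791912 to 13179170 reads per library. The day-0 libraries correlated with Pearson r = 0.708 across guides, and the day-15 libraries with r = 0.356; guides are not independent replicates. At day 15 the most abundant 1% of guides held 4.44% of the reads in clone 2 and 9.53% in clone 6, against 2.80% in each clone at day 0.

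Guides without a target were also lower at day 15. The median negative-control guide had a log2 change of -0.17 in clone 2 (SD 0.70 across 450 guides) and -0.49 in clone 6 (SD 0.97). Guides against targets other than the controls had medians of -0.16 and -0.41 (11160 guides), whereas control guides had medians of -1.98 and -1.83 (110 guides). Targeting and negative-control guides differed by -0.003 in median in clone 2 (permutation p = 0.932) and by 0.08 in clone 6 (permutation p = 0.112, adjusted p = 0.224), with targeting guides the higher in clone 6. Across all 765 tested targets the median change was -0.29, with 94.8% of targets below 0. After centring on the negative-control guides the median was 0.02 and 44.7% were below 0, and after median-of-ratios scaling 50.2% were below 0. Values below are on the deposited scale unless given as relative to the negative-control guides.

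Control guides stood apart from this background as a class, though not each guide did. Above the 95th percentile of the negative-control guides lay 0 of 110 control guides in clone 2 and 7 (6.36%) in clone 6. In both clones at once, 48 of 110 control guides lay below the 5th percentile of the negative-control guides (43.6%, 95% interval 34.7 to 53.0). Of the other targeting guides 130 of 11160 did so (1.16%, 0.982 to 1.38), and of the negative-control guides 5 of 450 (1.11%, 0.476 to 2.57). The last pair of shares did not differ by Fisher's exact test (p = 1).

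The first comparison asked which targets lost guides during growth. At day 15, 8 targets had fallen, and all 8 were controls. RPS15A, a protein of the small ribosomal subunit (chromosome 16, 18781295 to 18790334), had a change of -2.53 (SE 0.31, n = 2 libraries per time, adjusted p = 0.0468 by limma), or -2.21 relative to the negative-control guides. RPL7A of the large subunit was at -2.51 (SE 0.20), RPL32 at -2.47 (SE 0.24), RPS19 at -2.27 (SE 0.23), RPS18 at -2.05 (SE 0.20) and RPS21 at -1.63 (SE 0.21), with limma adjusted p between 0.0210 and 0.0468. RPA3, a subunit of the single-strand DNA binding protein RPA, fell by 1.47 (SE 0.20, limma adjusted p = 0.0468). RPL7A lay at -2.52 in clone 2 and -2.50 in clone 6, and for each of these genes the values of both clones were at -1.38 or below.

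The remaining 4 controls did not pass. RPL8 was at -1.41 (SE 0.22, limma adjusted p = 0.0858), RPA1 at -1.36 (SE 0.39, limma adjusted p = 0.258) and PCNA, the replication clamp, at -1.28 (SE 0.41, limma adjusted p = 0.269). RPL6 was at -1.57 (SE 1.14, limma adjusted p = 0.382), with the clones far apart. Compared with the unpaired fit, the paired fit pools the variance across targets more strongly, and all 12 controls passed in it. Its SE was 0.29 for RPL6, with clones at -3.14 and 0.01, and also 0.29 for RPL7A, whose clones lay close together. Over the kept guides the paired pass of RPL6 therefore does not show a fall in both clones. With no filter on low guides RPL6 lay at -3.31 in clone 2 and -1.76 in clone 6. With libraries centred on the negative-control guides 0 targets passed in the unpaired limma fit, although the controls stayed low. RPL7A was then at -2.20 with an SE of 0.34 in place of 0.20 (limma adjusted p = 0.438), and RPL32 was at -2.16 with an SE of 0.34.

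**Figure D1:**
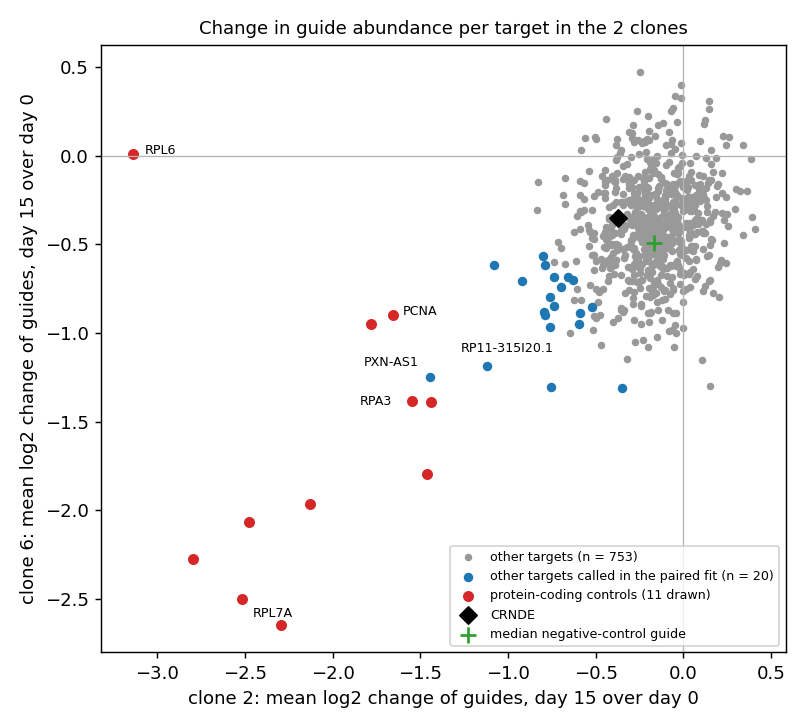
Mean log2 change of the guides of each target from day 0 to day 15, in clone 2 (x axis) and clone 6 (y axis), for 753 other targets (grey, or blue where the paired fit called them), the protein-coding controls (red, 1 of the 12 not drawn), CRNDE (diamond) and the median negative-control guide (cross). The controls lie toward the lower left, with RPL7A at -2.52 and -2.50, while RPL6, drawn over its 5 kept guides, lies at -3.14 and 0.01. CRNDE at -0.37 and -0.35 lies within the other targets.

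No lncRNA target passed the unpaired limma test with its variance trend. Without that trend it placed 11 targets lower, among them PXN-AS1 (adjusted p = 0.0419 by limma) and RP11-315I20.1 (adjusted p = 0.0369 by limma). At an unadjusted p under 0.05 the test with the trend had 128 targets lower and 0 higher. With the clone number as a replicate block, limma placed 32 targets lower, the 12 controls and 20 others, and 0 higher. Of these 20, PXN-AS1 was lowest, at -1.34 (paired SE 0.28, adjusted p = 7.93e-05 in the paired limma fit), or -1.02 relative to the negative-control guides. Its clones lay at -1.44 and -1.25, and 7 of its 10 guides were lower in both on the deposited scale. The median negative-control guide was also lower in both clones on that scale, and the background share for such counts was not computed. PXN-AS1 is annotated on chromosome 12 from 120201291 to 120212828, the annotated span of RPLP0, a ribosomal protein gene, lies 180 bp away, and PXN also lies within 1 kb (strands were not given in the table used). RP11-315I20.1 was at -1.15 (paired SE 0.28, paired limma adjusted p = 0.00176), with 22 of 33 guides lower in both clones.

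Others that passed in the paired limma fit were CTD-2616J11.14 at -1.03, RP11-661A12.7 at -0.86, RP11-486O12.2 at -0.85, RP11-269F19.2 at -0.84, PSORS1C3 at -0.84, RP11-483P21.6 at -0.83 and RP11-386G11.10 at -0.81. NFE4 was at -0.79, CTD-2616J11.9 at -0.78, AC010761.8 at -0.77, MIR210HG at -0.74 and RP11-411B10.2 at -0.72. Relative to the negative-control guides these changes ran from -0.70 for CTD-2616J11.14 to -0.39 for RP11-411B10.2. Among these targets the clones lay furthest apart for RP11-483P21.6, at -0.35 in clone 2 and -1.31 in clone 6 (unpaired limma adjusted p = 0.289). Random guide sets placed 14 targets lower and α-RRA 16, and 13 targets were lower by these and the paired fit alike. Of those 13, the targets outside the controls were PXN-AS1, RP11-315I20.1 and RP11-386G11.10. The paired calls have 1 residual degree of freedom and a pooled variance of infinite prior weight, and in simulated data with 40 targets lowered that fit made 10 false calls, all of lower. With the block, limma left 0 lower when libraries were centred on the negative-control guides and 15 after median-of-ratios scaling. These were 9 controls and 6 others, including PXN-AS1 and RP11-315I20.1 but not RP11-386G11.10. With guides summed per target RP11-386G11.10 was at -0.05, against -0.43 for PXN-AS1 and -0.47 for RP11-315I20.1.

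The opposite direction asked which targets gained guides. The unpaired limma fit found 0 higher targets, with 0 at an unadjusted p under 0.05, and the paired limma fit also found 0. That lopsided tally belongs to the deposited scale: centred on the negative-control guides, unadjusted p under 0.05 was reached by 32 lower and 22 higher targets, and after median-of-ratios scaling by 35 and 21, with 0 of either passing by limma. The 5 targets with the smallest p in this direction were RP11-44N11.1 at 0.23 (SE 0.12, limma adjusted p = 0.303), RP11-753H16.5 at 0.19, RP1-232P20.1 at 0.17, FTO-IT1 at 0.16 and CTD-2532K18.2 at 0.20. Relative to the negative-control guides RP11-44N11.1 was at 0.56 and FTO-IT1, which lies within FTO on chromosome 16, at 0.49. Random guide sets placed 2 targets higher, 1 of them RP11-44N11.1 (permutation, adjusted p = 0.00974). α-RRA placed 0 higher, but there a target also had to lie above 0 on the deposited scale, where 94.8% of targets lay below 0. That count therefore says little about gained guides.

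CRNDE, the lncRNA in the series title, had 40 guides, more than most targets. It is annotated on chromosome 16 from 54918863 to 54928886, and IRX5, a homeobox gene, begins 1979 bp away. Its change was -0.36 (SE 0.14, n = 2 libraries per time, limma adjusted p = 0.289), with -0.37 in clone 2 and -0.35 in clone 6. This did not pass, and in the paired limma fit the adjusted p was 0.279. Relative to the negative-control guides the change was -0.03. On the deposited scale, where the median negative-control guide also fell in each clone, 21 of the 40 guides were lower in both clones. When guides were summed before the log2 step the value was 0.24, above 0.

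Taken in table order in sets of 10, the CRNDE guides had mean changes of -0.25, -0.32, -0.78 and -0.10. These sets were formed after the data were seen. The third set was at -0.86 in clone 2 and -0.70 in clone 6 (SE 0.17, limma adjusted p = 0.182 over 1140 sets), and it passed in the paired limma fit (adjusted p = 0.0269). One guide of this set lay at -2.98 in clone 2 and -4.05 in clone 6.

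**Figure D2:**
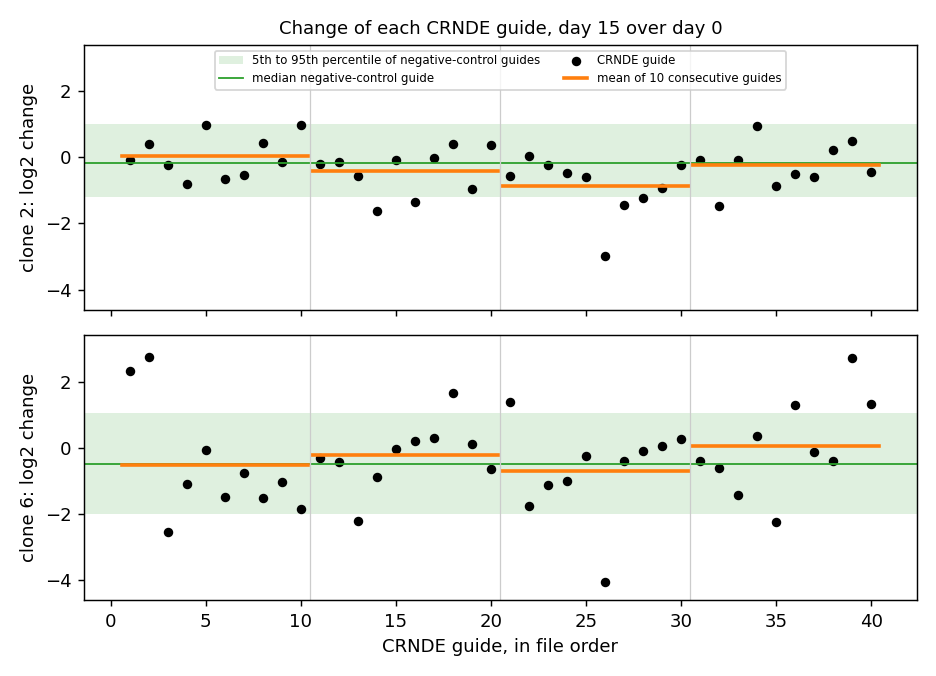
Log2 change from day 0 to day 15 of each of the 40 CRNDE guides (points, in table order), in clone 2 (top) and clone 6 (bottom), with the mean of each 10 consecutive guides (orange), the median negative-control guide (green line) and the 5th to 95th percentile of negative-control guides (green band). The set means lie between -0.86 and 0.03 in clone 2 and between -0.70 and 0.05 in clone 6, and 1 guide of the third set lies below the band in both clones.

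The gene lists asked whether classes of targets moved together. The 9 ribosomal protein genes fell as a list, with a median of -2.27 (camera adjusted p = 6.42e-15; fry adjusted p = 0.0257), and 7 of them had fallen singly, or 8 when adjusted over the list alone. With an estimated correlation the camera adjusted p was 0.321, so the call did not hold there. Among lncRNA lists no member passed over all targets by limma. MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, lay at -0.74 (SE 0.17) and passed by limma when adjusted over the list alone, both among 4 microRNA host genes (median -0.31) and among 5 lncRNAs at renal carcinoma genes (median -0.36, camera adjusted p = 0.712). It passed in the paired limma fit as well (adjusted p = 0.0216), but not with the block after median-of-ratios scaling (-0.45, limma adjusted p = 0.0928), nor by random guide sets (permutation, adjusted p = 0.671) or α-RRA (permutation, adjusted p = 0.841). Relative to the negative-control guides it lay at -0.41.

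The 6 measured snoRNA host genes had a median of -0.31 and 0 passed, also adjusted over the list alone (camera adjusted p = 0.712), with SNHG7 at -0.43 and ZFAS1 at -0.13. Of 6 lncRNAs studied in cancer 0 passed, also adjusted over the list alone (median -0.27, camera adjusted p = 0.847), with LUCAT1 at -0.42, NEAT1 at -0.27 and MALAT1 at -0.12. The 6 lncRNAs named for a housekeeping gene had a median of -0.32 (camera adjusted p = 0.712) and 0 passed, though DDX11-AS1 at -0.71 passed in the paired limma fit when adjusted over the list alone. Medians were -0.30 for 73 antisense names (camera adjusted p = 0.380), -0.27 for 39 intergenic names (camera adjusted p = 0.712) and -0.23 for 3 divergent names, each with 0 passing by limma over all targets and adjusted over the list alone. In the paired limma fit 1 antisense name passed, PXN-AS1. The list of housekeeping structured RNAs had 0 measured members.

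The clones were compared to find targets that behaved differently in each. RPL6, a protein of the large ribosomal subunit, differed between them, at -3.14 in clone 2 and 0.01 in clone 6 over 5 kept guides (difference -3.15; random guide sets, permutation, adjusted p = 0.0153). It was the only one of 765 targets to pass, and the test compares these libraries, since each clone had 1 library per time. With all 10 RPL6 guides, including those of few reads, the values were -3.31 and -1.76, below 0 in both clones. The difference of -1.55 still passed (permutation, adjusted p = 0.0160). With a pseudocount of 10 and the 5 kept guides the difference was -1.70 and did not pass (permutation, adjusted p = 0.0918). FAM13A-AS1, at -0.44 and 0.21, did not pass (permutation, adjusted p = 0.497). Neither did targets with clones further apart, such as ALG13-AS1 at 0.20 and -0.80. Across targets the changes in the clones correlated with Pearson r = 0.486 and Spearman rho = 0.193, or with r = 0.216 and rho = 0.162 without the controls; targets are not independent replicates.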

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

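In this part the tests of the negative-control shift, of counting error, of starting abundance and of a shared guide property were chosen after the result was seen. One result was singled out by a test between the clones. RPL6 differed by -3.15 on the log2 scale between clone 2 and clone 6, over the 5 kept guides (permutation, adjusted p = 0.0153). With no filter on low guides the difference was -1.55 over 10 guides and still passed (permutation, adjusted p = 0.0160), and with a pseudocount of 10 it was -1.70 over 5 guides and did not pass (permutation, adjusted p = 0.0918). The filter uses the mean over all 4 libraries, so guides with reads in clone 6 at day 15 were kept more readily.

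Negative-control guides were lower at day 15 in both clones. In a table of RPM values this may arise when a minority of expanded guides takes a larger share of the reads. Median-of-ratios scaling, which does not follow the most abundant guides, brought their median change to -0.084 in clone 6 (bootstrap SE 0.06) and to 0.00 in clone 2 (SE 0.03). This does not decide, because the scaling by construction brings the median of most guides near 0 and the negative-control guides had fallen by about as much as the others. At a fixed library total the most abundant 1% of guides did take a larger share at day 15. They held 4.44% of the reads in clone 2 and 9.53% in clone 6, against 2.80% in each clone at day 0. How far this accounts for the fall of the negative-control guides stays open, and no biological explanation was tested.

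The same guides spread widely, with SDs of 0.70 and 0.97. Read counting error alone would give 0.08 and 0.09, and the observed SDs were 8.71 and 10.7 times as large, which argues against counting error. A guide property that acts alike in both clones was argued against as the main source of the spread. The changes in the clones correlated weakly (Pearson r = 0.114 across 450 guides, 95% interval 0.0218 to 0.204). That interval is wholly positive, so a smaller shared part stays open. For low starting abundance, guides above the median day-0 level had SDs 0.783 (bootstrap 95% interval 0.661 to 0.926) and 0.873 (0.752 to 1.02) times those of guides below it, which did not decide. Drift from a limited number of cells per guide could act separately in each clone and stays open, as it was not tested.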

How the results depend on the processing

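Here the sets of negative-control guides, voom, scaling with the block, and the sets of 10 guides were chosen after the data were seen. The count of 8 lower targets became 32 in the paired fit with the clone as a replicate block, 14 with random guide sets, 16 with α-RRA, 17 with sets of negative-control guides, and 0 with a pseudocount of 10, a minimum of 50 RPM, the median over guides, guides summed per target, centring on the negative-control guides, centring with the replicate block, median-of-ratios scaling and voom on recovered reads. Median-of-ratios scaling with the replicate block gave 15. With consecutive sets of 10 guides it was 4, and 36 with the replicate block. A minimum of 50 RPM removes guides that were lost by day 15. For the other settings the cause was not tested. With summed guides the named controls that had passed stayed below 0 but fell less, from -1.43 for RPL32 to -0.53 for RPS21. The 0 higher targets became 2 with random guide sets and 2 with sets of negative-control guides. The block did not change the call of CRNDE as a whole target (limma adjusted p = 0.289 without it and 0.279 with it). Among its consecutive sets of 10 guides, set 3 passed only with the block (limma adjusted p = 0.182 without it and 0.0269 with it).

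Leaving out 1 library gave 4 to 545 lower and 0 to 12 higher targets. Lower targets numbered 4 without the day-0 library of clone 2, 5 without that of clone 6, 545 without the day-15 library of clone 2 and 188 without that of clone 6, and higher targets 12 and 6 without the last pair. The lone library of a time is then assumed to vary like the other time's. CRNDE ranged from -0.42 to -0.31 in these fits, and passed without the day-15 library of clone 2 (-0.40, limma adjusted p = 0.00463) or of clone 6 (-0.32, limma adjusted p = 0.0425). It reversed to 0.24 with summed guides and to 0.28 with voom (limma adjusted p = 0.863 and 0.843), without passing; over all its alternatives with a test the adjusted p ran from 0.00463 upwards to 1.

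RP11-483P21.6 reversed to 0.047 with summed guides, and RPL6 ranged from -3.40 to 0.27 when 1 library was left out, the latter without the day-15 library of clone 2. With an estimated correlation 0 lists passed in place of 1, and with a pseudocount of 10 the clone difference had 0 targets in place of 1. Of the comparisons of single named targets other than CRNDE with a tested alternative, 513 kept direction and side of the threshold, 73 lost and 89 gained the call and 2 reversed. In clone 6 alone, without a test, RPL6 lay at 0.01 over its kept guides and at -1.76 with no filter on low guides. Scaling to the library total equals the deposited scale and moves nothing. The negative-binomial count tests, planned only for raw counts, were not run.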

Other observations

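All tests of this part were chosen after the data were seen. Ribosomal control guides were already less abundant than negative-control guides at day 0, by a median of -0.79 in clone 2 and -0.58 in clone 6 (80 guides, permutation p = 1e-05 in each, the smallest that 100000 permutations can give). The 30 guides against PCNA, RPA1 and RPA3 were at -0.08 and 0.16. No earlier sample was analysed here.

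In some targets with many guides, part of the guides passed in the paired limma fit. There, 18 sets of up to 10 guides from 13 targets with more than 10 guides were lower. None of the 18 passed in the unpaired limma fit (smallest adjusted p = 0.0640), so these calls hold in the paired fit alone. Across whole targets the paired fit had the larger median SE (0.213 against 0.176) and a pooled variance of infinite prior weight. The calls thus need not come from taking out clone differences. The paired fit has 1 residual degree of freedom and made false calls of lower on simulated data. PCBP1-AS1, with 190 guides, had its set 17 at -2.27, set 18 at -1.29 and set 19 at -1.12, while its mean lay at -0.45 in each clone. Its annotation overlaps PCBP1, which encodes an RNA-binding protein. Set 2 of RP11-269F19.2 was at -1.54 and set 2 of DDX11-AS1, annotated 13 bp from the helicase gene DDX11, at -1.14.

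Consecutive sets of guides of 1 target thus differed in their change. Chance order was argued against over 196 targets, since shuffling guides within targets gave a spread as large in a share of 0.0005, the smallest that 2000 shuffles can give. For CRNDE alone chance order stays open, as shuffling its guides gave a set as low as the third in a share of 0.213. Whether a single guide accounts for that set also stays open. Without its lowest guide the set lay -0.87 standard errors from the negative-control mean. This does not decide, because taking away the lowest guide raises the mean of any set. Use of separate promoters by the sets stays untested, as guide positions were not used here.

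A hypothesis for PXN-AS1 is that its guides may repress RPLP0, whose annotated span lies 180 bp away. PXN also lies within 1 kb of PXN-AS1, and its part was not tested. The other 7 matched targets within 1 kb of a coding gene of the listed housekeeping families differed from the remaining 135 by a mean of -0.029 (bootstrap 95% interval -0.22 to 0.16, permutation p = 0.657). This does not decide for PXN-AS1, because 0 of the 7 lie beside a ribosomal protein gene and some neighbours, such as POLDIP3 and RPS6KA2, match a family by name alone. That reading of the test was set after its value was seen.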
